A study of Homo sapiens with 12 samples.

How the data were processed

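Messenger RNA was profiled in 12 libraries from 786-O, an established clear cell renal carcinoma line that lacks a functional VHL protein. Cells carried a lentiviral hairpin against GFP, which serves as the control (shGFP), or 1 of 3 hairpins against RARRES2, the gene of the secreted adipokine chemerin (shRARRES2_1, shRARRES2_2 and shRARRES2_3). Each of the 4 groups held 3 libraries, and group and replicate number were read from the sample titles.

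The deposited values are a depth-scaled signal per gene, TMM-normalized CPM, which the authors gave for 58381 genes. Per the submitters' processing notes, CASAVA, Trim Galore 0.6.1, STAR 2.5.2 and edgeR were used with the hg38 (GRCh38) build; the annotation used for counting is not given in the sources used here. Plain CPM had been assumed when the tests were fixed, but the deposited columns carry library scaling factors of 0.788 to 1.15 and the sums of 4 of them exceed that of plain CPM. The choice of test was not altered by this. Within each column all values were whole multiples of the value of 1 read. Dividing by it gave whole reads for 100% of the values at a tolerance of 1e-06, so the depth of each library is known. It ranged from 12599400 to 23594200 reads on genes, and 3 reads corresponded to 0.131 to 0.223 CPM. Counting error is therefore small against the spread between libraries for genes of several CPM, and large for genes near 1 CPM.

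Of 58381 gene identifiers, 58261 matched GENCODE 29 after the version suffix was removed, as did 15224 of the 15236 genes tested; coordinates are GRCh38, 1-based. Gene names shared by several identifiers occurred in 1733 entries, so identifiers were used throughout. Whether counting used strand is not stated, so a gene and its antisense partner may share reads, and close paralogs such as KRT81 and KLRC1 with their neighbouring family members are uncertain in the same way.

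Genes with at least 1 CPM in at least 3 libraries were kept. Values were transformed as log2(CPM + 1), and limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries with group means only, eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. This gave 8 residual degrees of freedom before moderation. All log2 changes are on the log2(CPM + 1) scale, which understates the changes of genes with low values. Each hairpin was compared with shGFP, a gene was counted as shared when all 3 comparisons passed with 1 sign, and a moderated F-test compared the 3 hairpins. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 90 tests, with an estimated correlation and with fry beside it. The 30 lists covered the chemerin system, HIF targets and components, lipid and coenzyme Q metabolism, ferroptosis, respiration, glycolysis, stress, interferon, inflammation, p53, proliferation, matrix, epithelial and renal genes, retinoid response, the small RNA pathway, histones, ribosomal proteins and markers of leukocytes, endothelium and fibroblasts. Lists of keratinocyte markers and of small nucleolar RNA host genes were added later.

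The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named RARRES2, its receptors, EPAS1 and KLF6; up to 12 shared genes in each direction; for each hairpin, the 6 genes that rose and the 6 that fell most, with 5 CPM in the higher group and no overlap between groups; the 6 leading genes of the F-test; and up to 4 members of each list as examples, whether or not they passed. RARRES2 alone was also compared by exact permutation tests, computed in R.

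The limma step was tested on simulated data for the comparison of shRARRES2_1 with shGFP, on 14855 to 14900 genes. It recovered 2.67% of genes changed by a log2 of 1 and 90.3% of genes changed by a log2 of 3, and 9.71% of its calls were false. edgeR 4.0.16 recovered 1.67% and 90.7% with 6.10% false, and DESeq2 1.42.0, in 1 simulation, 7% and 98% with 33.1% false. The simulated libraries were drawn independently of each other, whereas the real ones paired across groups. These rates therefore need not hold for the real data. The tests of gene lists were tried on simulated lists as well. In the real data the lists called had estimated correlations of 0.0742 (epithelial junctions) to 0.912 (mitosis), above the preset 0.01. How often unshifted lists with such correlations are called was not tested, so the simulated counts that follow cannot give that rate. A simulated shifted list had camera p = 2.27e-18 with the preset correlation and p = 8.96e-06 with an estimated one, and 1 and 0 of 20 unshifted lists had p under 0.05; fry gave p = 4.21e-06 and 2 of 20.

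Alternatives covered other pseudocounts, filters, scalings, spread estimates, thresholds, a replicate block, edgeR and DESeq2 on recovered reads, leaving out each library in turn and, chosen after seeing the data, removal or averaging of libraries that lay unusually close, 2 surrogate variables (sva 3.50.0) and the mean of the hairpins. Short sequences in 3' untranslated regions were taken from the GENCODE 29 annotation with Python 3.11.15 and numpy 2.4.6. Before these, 2 other fits were tried and not used. Library weights estimated by limma did not converge and gave shRARRES2_3 replicate 3 a weight of 49.1, at which 2942, 844 and 2692 genes were called for the 3 hairpins. edgeR with its own filter called 3, 4 and 1. Figures were drawn with matplotlib 3.10.9.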

Results

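The transcriptome of 786-O cells was compared between a control hairpin and 3 hairpins against RARRES2, with 3 libraries in each of the 4 groups. Recovered depth was 12599400 to 23594200 reads per library, and 20932 to 27603 genes had at least 1 read. Mitochondrial transcripts made up 3.69% to 6.13% of the reads. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

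Libraries did not group by hairpin alone. The nearest library by correlation of log2 values belonged to another group for 6 of the 12 libraries. shGFP replicate 2 lay closest to shRARRES2_3 replicate 2 (r = 0.982), shRARRES2_1 replicate 1 to shRARRES2_3 replicate 1 (r = 0.981) and shRARRES2_2 replicate 3 to shRARRES2_3 replicate 3 (r = 0.975). Correlations within groups were 0.924 to 0.974 for shGFP, 0.940 to 0.997 for shRARRES2_1, 0.961 to 0.970 for shRARRES2_2 and 0.864 to 0.954 for shRARRES2_3. The highest of these, 0.997, was between shRARRES2_1 replicates 2 and 3. These are correlations across genes, which are not independent replicates.

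**Figure D1:**
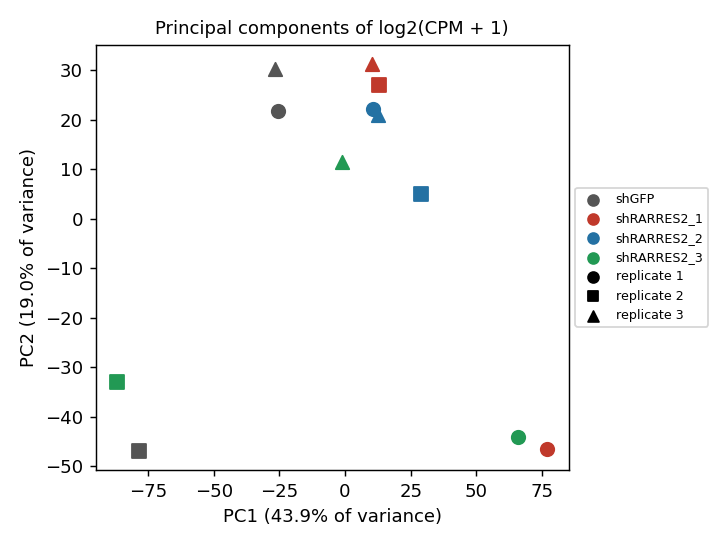
Scores of the 12 libraries on the first (43.9% of variance) and second (19.0%) principal components of log2(CPM + 1), coloured by group with a marker shape for each replicate number. shGFP and shRARRES2_3 replicates 2 lie together at the left, and shRARRES2_1 and shRARRES2_3 replicates 1 together at the right.

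RARRES2, which encodes the secreted chemoattractant chemerin, was lower in every hairpin library than in every control library. The gene (ENSG00000106538.9) lies on the minus strand of chromosome 7 at 150338317 to 150341674. The 3 shGFP libraries had 808.8, 483 and 469 CPM (mean 587 ± 192, SD, n = 3). The means were 39.7 ± 1.91 CPM with shRARRES2_1, 73.2 ± 19.5 with shRARRES2_2 and 44.8 ± 4.72 with shRARRES2_3 (SD, n = 3 each), or 6.76%, 12.5% and 7.62% of the control. The highest hairpin library, shRARRES2_2 replicate 1, had 92.6 CPM. On the log2 scale RARRES2 fell by 3.81, 2.97 and 3.64 (SE 0.28 each), with limma adjusted p = 9.49e-05, 0.00165 and 1.60e-04 after Benjamini-Hochberg adjustment. An exact two-sided permutation test gave p = 0.10 for each hairpin, the smallest that 3 against 3 libraries allow, and p = 0.00455 for the 9 hairpin libraries against the 3 controls. RARRES2 was higher with shRARRES2_2 than with the other hairpins together by an exact permutation test on CPM (two-sided p = 0.0119, the smallest that its 84 splits allow). That test was not among those fixed in advance. It also counts shRARRES2_1 replicates 2 and 3, which were nearly alike, as separate libraries. The limma F-test between hairpins gave an adjusted p = 0.355.

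**Figure D2:**
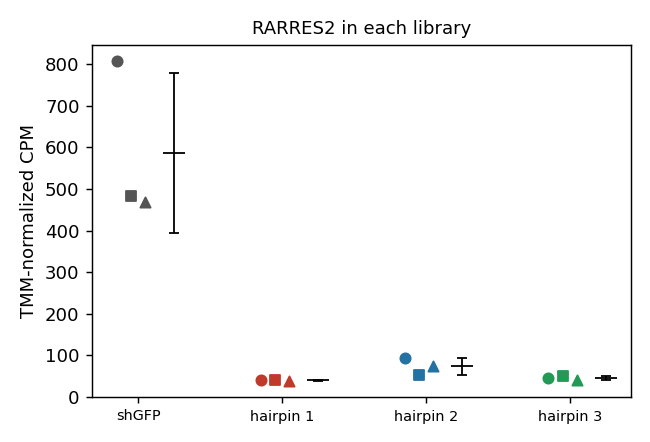
RARRES2 in TMM-normalized CPM in each library (circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of 3 libraries to the right of each group. The 9 hairpin libraries had at most 92.6 CPM, below the lowest control library at 469 CPM.

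Among the chemerin receptors, CCRL2, which binds chemerin without classical G-protein signalling, rose with shRARRES2_1. Its level went from 0.299 ± 0.344 CPM to 9.43 ± 3.26 CPM (SD, n = 3; log2 change 2.99, SE 0.39, limma adjusted p = 0.00929). With shRARRES2_2 and shRARRES2_3 it was at 1.37 and 1.98 CPM, without a call (limma adjusted p = 0.352 and 0.876), and the F-test between hairpins gave a limma adjusted p = 0.0646. Its log2 changes with these hairpins were 0.87 and 1.12, and its unadjusted limma p was under 0.05 with all 3. GPR1, the other measured receptor, had 4.24 ± 6.13 CPM in shGFP and 4.38, 4.08 and 8.81 CPM with the hairpins (limma adjusted p = 0.632, 0.724 and 0.876). CMKLR1, the main signalling receptor, was at or below 0.238 CPM (0 to 4 reads) in all 12 libraries and was not tested. The CCRL2 call ended without shGFP replicate 1, shGFP replicate 3 or shRARRES2_1 replicate 2 (limma adjusted p = 0.1, 0.0668 and 0.0544).

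With shRARRES2_1, 26 of 15236 genes changed against shGFP, 15 up and 11 down. GOLGA7B, of a family of Golgi-associated proteins, rose from 1.27 ± 0.553 to 52.1 ± 18.5 CPM (log2 change 4.50, SE 0.48, limma adjusted p = 0.00355). SERPINB2, an inhibitor of urokinase, rose from 0.161 to 19.7 CPM (3.89, limma adjusted p = 0.00896). The hair keratin KRT81 rose from 0.946 to 16.6 CPM, the interferon regulatory factor IRF8 from 0.450 to 11.1 CPM and the lectin-like receptor KLRC1 from 0.144 to 5.64 CPM (log2 changes 3.18, 3.06 and 2.41, limma adjusted p = 0.0373, 0.0474 and 0.0279). Genes that fell included MARCKSL1, an actin-binding protein, from 75.1 to 13.8 CPM (log2 change -2.35), and MTPN, myotrophin, which binds actin capping protein, from 309 to 66.3 CPM (-2.24), with limma adjusted p = 0.00882 and 0.00896. The receptor kinase gene EPHB4 fell from 7.72 to 0.728 CPM (-2.23, limma adjusted p = 0.0489). The small nucleolar RNA host genes C6orf48 and GAS5 fell from 468 to 98.8 CPM and from 317 to 79.5 CPM (-2.15 and -1.98, limma adjusted p = 0.0397 and 0.0373). At an unadjusted p under 0.05 there were 2538 genes, against 762 expected by chance.

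Of the 10 genes named above for shRARRES2_1, GOLGA7B alone kept its call in every fit that left out 1 compared library (limma adjusted p up to 0.0408). MARCKSL1 and MTPN lost it without shGFP replicate 3 (0.0668 each) or shRARRES2_1 replicate 2 (0.0529 each), MARCKSL1 also without shRARRES2_1 replicate 3 (0.0565) and MTPN without shGFP replicate 1 (0.0681), all limma adjusted p. SERPINB2, tested in 3 of the 6 fits because it otherwise fell under the expression filter, lost it without shGFP replicate 1 or 3 (limma adjusted p = 0.0828 and 0.0668). IRF8 and EPHB4 lost it without any 1 of the 6 libraries (limma adjusted p up to 0.254 and 0.291). KRT81, KLRC1 and GAS5 kept it only without shRARRES2_1 replicate 1 (limma adjusted p = 0.0391, 0.00129 and 0.0123), and C6orf48 only without shGFP replicate 2 (0.045). The count of 26 became 4, 9 and 3 without shGFP replicates 1, 2 and 3, and 3 and 5 without shRARRES2_1 replicates 2 and 3. Leaving out a library that only informs the spread also moved it, to 11, 10 and 8 without shRARRES2_2 replicates 1, 2 and 3 and to 80, 195 and 10 without shRARRES2_3 replicates 1, 2 and 3. With shRARRES2_1 replicates 2 and 3 averaged it was 6. edgeR on recovered reads called 3 genes, 0 up and 3 down, so GOLGA7B and the other raised genes had no call there. DESeq2 called 497.

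**Figure D3:**
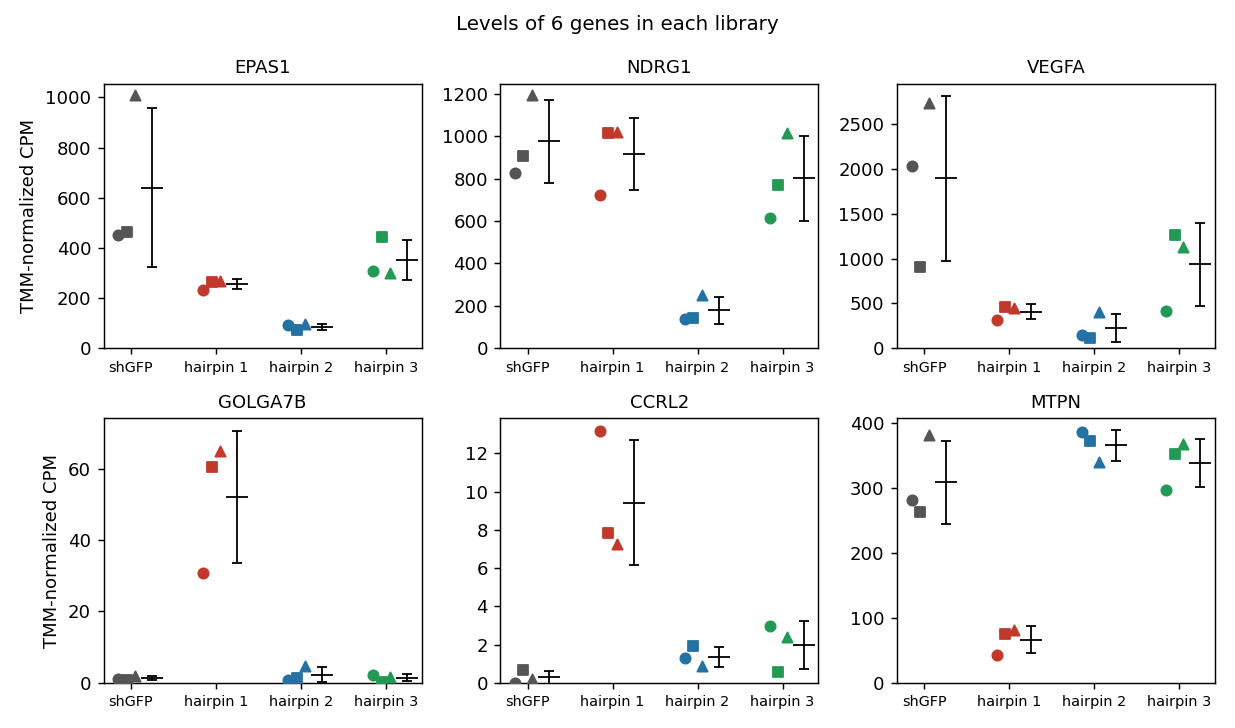
TMM-normalized CPM of 6 genes in each library (circle, square and triangle for replicates 1, 2 and 3; hairpins 1, 2 and 3 are shRARRES2_1, shRARRES2_2 and shRARRES2_3), with the mean and SD of 3 libraries to the right of each group. GOLGA7B and CCRL2 were highest and MTPN lowest with shRARRES2_1 (means 52.1, 9.43 and 66.3 CPM), and EPAS1, NDRG1 and VEGFA were lowest with shRARRES2_2 (86.1, 177 and 222 CPM).

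Of the 30 gene lists, 7 were called by camera with shRARRES2_1 at the preset correlation, and each of them had an adjusted p = 0.987 with an estimated correlation. DNA replication genes rose as a group, with 31 of 32 members above 0 and a median log2 change of 1.24 (camera adjusted p = 9.74e-06), and mitosis genes did so with 26 of 27 members and a median of 1.18 (0.00123). FEN1, the flap endonuclease, had 78.3 CPM against 31.1 and BIRC5, survivin, 262 ± 227 against 58.0 ± 39.2 CPM (limma adjusted p = 0.206 and 0.302). Interferon response genes rose as a group (34 of 36 members above 0, median 1.52, camera adjusted p = 4.00e-05). RSAD2, viperin, had 65.4 ± 54.6 against 9.80 ± 14.3 CPM and USP18, which restrains interferon signalling, 39.6 against 10.1 CPM (limma adjusted p = 0.321 and 0.247). Cytosolic ribosomal protein genes fell as a group, 62 of 70 members below 0 with a median of -0.44 (camera adjusted p = 1.42e-04); RPL37 had 666 against 1455 CPM (limma adjusted p = 0.213). Genes of fatty acid oxidation (20 of 22 above 0, median 0.51), glycolysis (18 of 22, 0.45) and epithelial junctions (13 of 18, 0.72) also rose as groups, with camera adjusted p = 0.00988, 0.0393 and 0.0494. No member of these 7 lists passed the test, over all genes or adjusted over the list alone. With 2 surrogate variables mitosis genes were called in the other direction (median -0.28, camera adjusted p = 0.00532). The calls then ended for DNA replication (median 0.04, camera adjusted p = 0.953), interferon response (0.30, 0.375), fatty acid oxidation (0.03, 0.565), glycolysis (0.06, 0.806) and epithelial junctions (0.27, 0.365), and ribosomal proteins stayed lower (-0.67, 7.93e-27).

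Several of these groups moved with libraries that paired across hairpins. The median level of the mitosis genes was 13.3 CPM in shGFP replicate 2 and 16.8 CPM in shRARRES2_3 replicate 2, against 53.7 to 180.0 CPM in the other 10 libraries. The DNA replication genes had medians of 15.3 and 16.6 CPM in the same libraries and 27.1 to 107 CPM elsewhere. For interferon response genes the medians were 5.90, 4.49 and 10.8 CPM in shGFP, shRARRES2_3 and shRARRES2_2 replicates 2, against 19.8 to 96.5 CPM in the rest; the highest, 96.5 CPM, was a control, shGFP replicate 3, above the shRARRES2_1 libraries at 76.4 to 83.8 CPM. The interferon call ended with 4 paired libraries removed (camera adjusted p = 0.0594). Fatty acid oxidation genes were highest in shRARRES2_1 and shRARRES2_3 replicates 1 (65.9 and 59.7 CPM, others 20.8 to 45.4), as were glycolysis genes (529.9 and 449 CPM, others 174 to 312). Without shGFP replicate 2 the shRARRES2_1 calls ended for mitosis (median 0.24 in place of 1.18, camera adjusted p = 0.536), ribosomal proteins (0.186) and epithelial junctions (0.0706). The same control library had by far the highest median of keratinocyte markers (65.6 CPM, at most 4.65 CPM elsewhere). Carry-over from other cells was not tested as a source of these calls. Ribosomal protein genes had medians of 411 and 377 CPM in shRARRES2_1 replicates 2 and 3, which were nearly alike. In shRARRES2_1 replicate 1 the median was 1158 CPM, above the controls at 627, 1048 and 548 CPM. The lower ribosomal level with this hairpin therefore rested on replicates 2 and 3. The ribosomal call also ended without shRARRES2_1 replicate 2 or 3 (camera adjusted p = 0.111 and 0.281), fatty acid oxidation without shGFP replicate 3 or shRARRES2_1 replicate 1 (0.0611 and 0.213). Glycolysis lost its call without shGFP replicate 1 or shRARRES2_1 replicate 1 (0.0728 and 0.464). Epithelial junctions lost theirs without shGFP replicate 3, shRARRES2_1 replicate 1, shRARRES2_1 replicate 2 or shRARRES2_2 replicate 1 (camera adjusted p = 0.0981, 0.0784, 0.053 and 0.0582). Their medians were then 0.81, 0.67, 0.76 and 0.72, against 0.72 with all libraries, so the size of the change was largely kept. The number of lists called with shRARRES2_1 was 4 without shRARRES2_1 replicate 1.

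With shRARRES2_2, 7 genes changed against shGFP, 1 up and 6 down. EPAS1, the hypoxia-inducible factor subunit that predominates in 786-O cells, fell from 641 ± 319 to 86.1 ± 11.8 CPM (SD, n = 3; log2 change -2.78, SE 0.32, limma adjusted p = 0.0107). The gene (ENSG00000116016.13) lies on the plus strand of chromosome 2 at 46293667 to 46386703. The libraries had 449.6, 464 and 1008 CPM in shGFP and 90.6, 72.6 and 94.9 CPM with shRARRES2_2. NDRG1, a hypoxia-induced stress gene, fell from 975.4 ± 194 to 177 ± 63.9 CPM (-2.49, limma adjusted p = 0.0255), and BHLHE40, a hypoxia-induced transcription factor, from 388 to 111 CPM (-1.83, 0.0371). RNASET2, a lysosomal ribonuclease, fell from 109 to 27.3 CPM (-1.99, limma adjusted p = 0.0255). A further gene that fell is not named here. HBEGF, a ligand of the EGF receptor, rose from 4.36 to 21.3 CPM (2.04, limma adjusted p = 0.0387). EPAS1 was at 255 CPM with shRARRES2_1 and 350.0 CPM with shRARRES2_3 (limma adjusted p = 0.154 and 0.876). Its log2 changes there were -1.22 and -0.79, and its unadjusted limma p was under 0.05 with each of the 3 hairpins. The 3 comparisons share the same controls. For the mean of the 3 hairpins, which includes shRARRES2_2, the EPAS1 change was -1.60 (limma adjusted p = 0.246).

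Between hairpins, EPAS1, NDRG1 and HBEGF differed by the F-test (limma adjusted p = 0.0441, 0.0152 and 0.0273), while RNASET2 and BHLHE40 did not pass it (0.0772 and 0.0878). The call of EPAS1 against shGFP ended without shRARRES2_2 replicate 1 or 2 (limma adjusted p = 0.0939 and 0.0897). NDRG1 and RNASET2 lost theirs also without shGFP replicate 1 (0.137 each) or 3 (0.183 each), and kept it without shGFP replicate 2 or shRARRES2_2 replicate 3. HBEGF and BHLHE40 kept a call only without shRARRES2_2 replicate 3 (limma adjusted p = 0.0349 and 0.0221). The count of 7 became 2, 11 and 2 without shGFP replicates 1, 2 and 3, and 1, 1 and 19 without shRARRES2_2 replicates 1, 2 and 3. It was 2 without shRARRES2_1 replicate 2, shRARRES2_1 replicate 3 or shRARRES2_3 replicate 3, and 14 and 119 without shRARRES2_3 replicates 1 and 2. At an unadjusted p under 0.05 there were 2085 genes. edgeR on recovered reads called 4, 0 up and 4 down, so HBEGF had no call there. DESeq2 called 345. With each library rescaled to a common total, 2 genes were called, 0 up and 2 down, in place of 1 up and 6 down.

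HIF target genes fell as a group with shRARRES2_2. Of 26 measured members 23 were below 0, the median log2 change was -0.81 and camera gave an adjusted p = 3.81e-09; the adjusted p = 0.806 with an estimated correlation (unadjusted 0.00896). Over all genes tested 2 members fell, NDRG1 and BHLHE40, and adjusted over the list alone 7 fell and 1 rose. VEGFA, the angiogenic growth factor, was at 222 ± 157 CPM against 1896 ± 922 CPM and IGFBP3, which binds insulin-like growth factors, at 151 ± 71.6 against 1163 ± 689 CPM (limma adjusted p = 0.111 each). For the mean of the 3 hairpins their log2 changes were -2.10 and -2.09 (limma adjusted p = 0.370 each). That mean includes shRARRES2_2, so it cannot tell whether these genes were lower with the other hairpins. By library, the median level of the list was 69.9, 78.0 and 102 CPM with shRARRES2_2, 152 to 193 CPM in shGFP and 116 to 166 CPM with the other hairpins. The list was lower with shRARRES2_2 than with shRARRES2_1 and than with shRARRES2_3 (camera adjusted p = 8.53e-08 and 5.69e-07; adjusted p = 0.793 for both with an estimated correlation). Among HIF components, EPAS1 fell, while HIF1A, the related alpha subunit, was at 113 against 316 CPM (limma adjusted p = 0.230) and the list was not called (camera adjusted p = 0.186). In fry's test for change in either direction, HIF targets and HIF components had an adjusted p = 1.08e-04 and 2.73e-05.

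Targets of ATF4 and the unfolded protein response also fell as a group with shRARRES2_2, with 20 of 26 members below 0 and a median of -0.60 (camera adjusted p = 2.06e-04; adjusted p = 0.987 with an estimated correlation, as for the 3 lists below). Adjusted over the list alone 3 members fell, and none over all genes tested. HERPUD1, which takes part in endoplasmic reticulum degradation, had 70.5 against 142 CPM and ASNS, asparagine synthetase, 1.497 against 4.64 CPM (limma adjusted p = 0.238 and 0.362). DNA replication (31 of 32 above 0, median 1.04) and mitosis genes (27 of 27, median 1.23) rose as groups (camera adjusted p = 7.56e-06 and 7.92e-04), with FEN1 at 79.6 CPM and BIRC5 at 156 ± 88.3 CPM (limma adjusted p = 0.260 and 0.489). Ribosomal protein genes fell as a group, 53 of 70 below 0 with a median of -0.18 (camera adjusted p = 0.0133). Without shGFP replicate 2 the calls for mitosis, whose median went from 1.23 to 0.26, and ribosomal proteins ended (camera adjusted p = 0.545 and 0.885). With 2 surrogate variables DNA replication and mitosis were not called (camera adjusted p = 0.242 and 0.726), whereas HIF targets, ATF4 targets and ribosomal proteins stayed lower (1.45e-11, 1.18e-07 and 9.38e-10). The number of lists called with shRARRES2_2, 5, became 9 without shGFP replicate 2 and 8 without shRARRES2_2 replicate 3.

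With shRARRES2_3, RARRES2 itself was the 1 gene that changed, while 10 gene lists were called by camera at the preset correlation, each with an adjusted p = 0.987 with an estimated correlation. Genes of cell division rose as groups: DNA replication with 32 of 32 members above 0 (median 0.72, camera adjusted p = 2.51e-06) and mitosis with 27 of 27 (0.87, 1.24e-04), with FEN1 at 62.8 ± 33.6 CPM and PLK1, the mitotic kinase, at 173 ± 183 against 37.2 ± 22.5 CPM (limma adjusted p = 0.876 each). Cholesterol synthesis genes rose as a group (23 of 24 above 0, median 0.68, camera adjusted p = 2.06e-04). Mitochondrial groups rose too: fatty acid oxidation (19 of 22 above 0, median 0.48, camera adjusted p = 0.00103), complex I (29 of 36, 0.40, 0.00148), coenzyme Q synthesis (10 of 11, 0.39, 0.00390) and complex IV with its assembly factors (25 of 31, 0.29, 0.0270). Matrix and mesenchymal genes fell as a group (27 of 33 below 0, median -0.38, camera adjusted p = 2.06e-04). TGFBI, a matrix protein induced by TGF-beta, had 2045 ± 555 against 4432 ± 2308 CPM (limma adjusted p = 0.876). Inflammatory cytokines and NF-kB targets (23 of 25 below 0, median -0.75) and HIF targets (18 of 26, -0.36) fell as groups, with camera adjusted p = 0.00127 and 0.0127. SOD2, the mitochondrial superoxide dismutase, had 1750 ± 1639 against 2902 ± 871 CPM and LOX, which crosslinks collagen, 127 ± 192 against 215 ± 30.7 CPM (limma adjusted p = 0.876 each).

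For shRARRES2_3 no member of the called lists passed over all genes tested, and 1 HIF target fell when adjusted over the list alone. With 2 surrogate variables the calls ended for DNA replication (camera adjusted p = 0.147), fatty acid oxidation (0.418), cholesterol synthesis (0.394), coenzyme Q synthesis (0.272), complex I (0.968) and complex IV (0.808), and remained for mitosis (median 0.40 in place of 0.87, 0.00122), matrix genes (-0.44 in place of -0.38, 1.34e-08), NF-kB targets (-0.25 in place of -0.75, 0.0409) and HIF targets (-0.28 in place of -0.36, 0.0291). Complex I genes were highest in shRARRES2_3 and shRARRES2_1 replicates 1 (85.6 and 76.8 CPM, others 35.3 to 59.4), as were cholesterol synthesis genes (134 and 109.5 CPM, others 32.4 to 88.8), fatty acid oxidation genes (59.7 and 65.9 CPM, others 20.8 to 45.4), and coenzyme Q synthesis genes in shRARRES2_3 replicate 1 (27.8 CPM, others 9.04 to 23.3). Without shRARRES2_3 replicate 1 the calls ended for DNA replication (camera adjusted p = 0.237), mitosis (0.257), fatty acid oxidation (0.354), coenzyme Q synthesis (0.116), complex I (0.492) and complex IV (0.745). Without shRARRES2_3 replicate 2 they ended for matrix genes (median -0.29, camera adjusted p = 0.153) and NF-kB targets (-0.23, 0.156). They also ended for HIF targets (-0.34, 0.0512) and complex IV (0.38 in place of 0.29, 0.0512), whose medians were no nearer 0 or hardly so. Mitosis also lost its call without shGFP replicate 2, where its median went from 0.87 to -0.03 (0.9004), cholesterol synthesis and complex IV without shGFP replicate 1 (0.0676 and 0.214), and HIF targets, complex I, complex IV and NF-kB targets without shGFP replicate 3 (0.401, 0.0854, 0.218 and 0.261). With shGFP and shRARRES2_3 replicates 2 both left out, an alternative chosen after seeing the data, the calls held for mitosis (median 0.95, camera adjusted p = 2.69e-07), matrix genes (-0.38, 0.00242), NF-kB targets (-1.10, 3.86e-04), HIF targets (-0.58, 0.00155) and complex IV (0.41, 0.00390). With 4 paired libraries removed, also chosen after seeing the data, they ended for NF-kB targets (median -0.32, camera adjusted p = 0.0648) and complex IV (0.24, 0.0872). The number of lists called, 10, became 16 without shRARRES2_3 replicate 3. Single genes with an unadjusted p under 0.05 numbered 506, below the 762 expected by chance; edgeR on recovered reads called 1 gene and DESeq2 16.

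**Figure D4:**
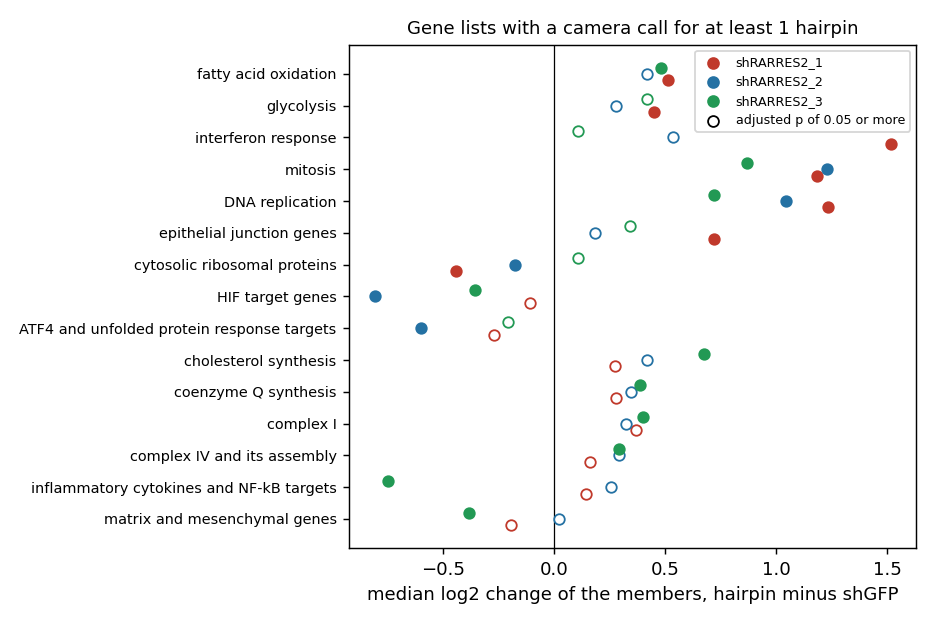
Median log2 change of the members of each gene list called by camera with at least 1 hairpin, against shGFP; filled points passed at the preset correlation and open points did not. DNA replication medians were 1.24, 1.04 and 0.72 and HIF target medians -0.11, -0.81 and -0.36 with shRARRES2_1, shRARRES2_2 and shRARRES2_3.

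RARRES2 was the 1 gene that changed the same way with all 3 hairpins. Independent lists of these sizes would share 2.84e-07 lowered genes. In 20 draws of unchanged groups, simulated from the spread within groups, at most 0 were shared. The control group was simulated as well, so the shGFP libraries themselves were not reused. RARRES2 is the target of all 3 hairpins, so neither value tests for a shared response beyond it. At an unadjusted p under 0.05, 112 genes moved the same way with all 3, 54 higher and 58 lower. EPAS1, lower, and CCRL2, higher, were among them. How many unchanged groups with shared controls would give was not estimated. The 112 genes therefore cannot be told apart from an effect of the shared controls. Among named genes, GAS5 had 79.5, 108 and 110 CPM against 317 CPM in shGFP (limma adjusted p = 0.0373, 0.123 and 0.730). KLF6, a transcription factor of the zinc-finger family, had 393, 292 and 250.5 CPM against 328 CPM (limma adjusted p = 0.620, 0.994 and 0.889). Across genes, log2 changes correlated at 0.70 between shRARRES2_1 and shRARRES2_2, and at 0.60 for each of these with shRARRES2_3. Unchanged groups simulated in this way against a shared simulated control group gave medians of 0.58, 0.61 and 0.61. The covariances were 0.314, 0.191 and 0.173 against simulated means of 0.113, 0.105 and 0.104, a difference of 0.201, 0.0856 and 0.0691. High percentiles of the simulated covariances were 0.439, 0.383 and 0.372, each above the observed value. Unchanged groups could therefore give covariances of this size, so no excess was established. The differences may come from the shared controls, which are too few to split.

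Between the 3 hairpins, 38 genes differed by the moderated F-test. GOLGA7B and MTPN led (limma adjusted p = 0.00926 each). MTPN had 66.3 CPM with shRARRES2_1 and 366 and 339 CPM with shRARRES2_2 and shRARRES2_3. RAB1A, a GTPase of transport from the endoplasmic reticulum to the Golgi, had 62.6, 213 and 201 CPM against 180.1 CPM in shGFP, and SERPINB2 19.7, 0.266 and 0.286 CPM (limma adjusted p = 0.0104 each). TNFRSF21, a death receptor, had 38.1, 37.2 and 6.64 CPM against 17.5 CPM in shGFP (limma adjusted p = 0.0104), and ABCC9, a subunit of ATP-sensitive potassium channels, 6.22, 0.807 and 0.276 CPM (0.0118). MARCKSL1 and KLRC1 also differed (limma adjusted p = 0.0125 and 0.0327), whereas KRT81, IRF8, EPHB4, C6orf48 and GAS5 did not pass (0.225, 0.157, 0.254, 0.406 and 0.709). Interferon response genes were higher with shRARRES2_1 than with shRARRES2_2 and shRARRES2_3 (medians 1.23 and 1.40, camera adjusted p = 1.17e-06 and 9.36e-07; adjusted p = 0.968 with an estimated correlation). The F-test count became 0 without shRARRES2_1 replicate 2 or 3, the libraries with r = 0.997, and 0 when these were averaged. It was 15 and 19 without shRARRES2_2 replicates 1 and 2, and 92 and 10 without shRARRES2_3 replicates 1 and 3; TNFRSF21 lost its call without shRARRES2_3 replicate 3 (limma adjusted p = 0.0656).

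The other 15 lists were not called by camera with any hairpin. In fry's test for change in either direction, 2 of them passed: HIF components with shRARRES2_2 (adjusted p = 2.73e-05) and the small RNA pathway with shRARRES2_1 (0.0224), in which PRKRA, a partner of Dicer, fell from 50.2 to 18.2 CPM (limma adjusted p = 0.0467; chosen after its values were seen). Their lowest camera adjusted p over the 3 hairpins was 0.0583 for fatty acid synthesis, 0.0761 for lipid uptake and droplets, 0.707 for ferroptosis restraint and 0.768 for ferroptosis promotion. It was 0.394 for the chemerin system, 0.186 for HIF components, 0.269 for mitochondrially encoded transcripts, 0.725 for p53 targets, 0.587 for the retinoid response, 0.661 for the small RNA pathway and 0.205 for replication-dependent histones. For genes of other cell types or lineages it was 0.145 (leukocyte), 0.0855 (endothelial), 0.235 (fibroblast and pericyte) and 0.766 (proximal tubule and renal lineage). HMOX1, heme oxygenase, a member of the ferroptosis promotion list, had 388, 311 and 57.1 CPM with the 3 hairpins against 100.5 CPM in shGFP (limma adjusted p = 0.101, 0.214 and 0.876) and differed between hairpins (limma F-test adjusted p = 0.0327).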

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

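The differences between hairpins below came from tests fixed before the values were seen, whereas the tests of swapped labels, non-coding share, a library counted again, an RNA prepared again and extent of RARRES2 loss were chosen after the result was seen. What drew attention was a difference between groups that share a target. By the limma F-test 38 genes differed between the hairpins, led by GOLGA7B and MTPN (limma adjusted p = 0.00926 each), RAB1A, TNFRSF21 and SERPINB2 (limma adjusted p = 0.0104 each) and ABCC9 (0.0118). Gene lists differed as well: 3 between shRARRES2_1 and shRARRES2_2, 2 between shRARRES2_1 and shRARRES2_3, and 4 between shRARRES2_2 and shRARRES2_3, by camera at the preset correlation. None of these 9 calls held with an estimated correlation (adjusted p of 0.793 to 0.968) or with fry (0.372 to 0.946). Of 100 splits of the 9 hairpin libraries into 3 groups of 3, the real grouping among them, 2 gave at least 38 genes. The highest other split gave 199. A grouping other than hairpin could therefore yield more genes, and the cause of that split was not tested. For genes shared by all 3 hairpins the real value was 1. It was reached by 3 of 100 splits of the 12 libraries, the real grouping again among them, with 12 in the highest other. The shared gene is RARRES2, the target of all 3 hairpins, so these splits do not test for a shared response beyond it.

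For 3 against 3 libraries the 10 possible splits are too few for a share under 0.05. As many genes as the real 26, 7 and 1 were called in 1, 1 and 2 of the splits for shRARRES2_1, shRARRES2_2 and shRARRES2_3, with 0, 0 and 5 in the highest other split. As many gene lists as the real 7, 5 and 10 were called in 6, 10 and 5 of the splits, with 13, 14 and 14 in the highest other. The number of lists called by camera at the preset correlation was thus also reached by groups that mix control and hairpin libraries.

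Libraries paired across groups, as with the number-2 libraries of shGFP and shRARRES2_3 and the number-1 libraries of shRARRES2_1 and shRARRES2_3. A swap of labels between shRARRES2_3 replicate 2 and a control was excluded, since RARRES2 was at 49.7 CPM there, against 469 CPM in the lowest control. RARRES2 was low with every hairpin, so its level cannot tell whether labels were swapped between hairpin libraries. Sequencing depth was excluded: after thinning to the lowest depth, first component scores correlated with the original ones at 0.999976. The share of non-coding transcripts placed 4 of the 4 libraries at its extremes, 2.54% and 2.94% in the first pair and 0.959% and 0.982% in the second, so a difference in RNA quality or preparation may contribute. Culture density or cell cycle state would be a biological alternative, and no design group allowed it to be tested, so no biological explanation was tested.

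shRARRES2_1 replicates 2 and 3 were nearly alike (r = 0.997). A single library counted again under another number was excluded, since their recovered reads differed by a chi-square of 2.95 per degree of freedom. The next closest pair had 47.0, so the spread between these libraries was far nearer to counting error than that of any other pair. A single RNA or culture used for both could give this and remains open. No biological explanation was tested.

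HIF target genes were lower with shRARRES2_2 than with the control and the other hairpins by camera at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.806 against shGFP and 0.793 against each other hairpin). RARRES2 was least reduced with this hairpin, which runs against the extent of RARRES2 loss as an explanation but does not exclude it. With an estimated correlation the list differed from the other hairpins only on unadjusted values (camera unadjusted p = 0.0142 and 0.0192). RARRES2 itself did not pass the limma F-test between hairpins. GC content and gene length were excluded, as the median log2 change was -0.85 after their trend was removed, against -0.81 before. With 2 surrogate variables for library structure the median was -1.18 and EPAS1 was at -2.72 (limma adjusted p = 0.00318). These variables were estimated with the groups in the model. Library structure that coincides with the shRARRES2_2 group therefore cannot be excluded in this way. An effect of this hairpin on EPAS1 that is unrelated to chemerin could account for the difference and is taken up under the seed matches of the hairpin.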

How the results depend on the processing

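The alternatives that remove or average libraries, the surrogate variables and the mean of the hairpins were chosen after the result was seen; the others were fixed in advance. The fall of RARRES2 kept its direction and its call under every alternative but 1: with 4 paired libraries removed, which leaves shRARRES2_3 with 1 library assumed to vary like the other groups, its change there was -3.90 (limma adjusted p = 0.103). Genes changed with shRARRES2_1 numbered 26, and 7 with shRARRES2_2, 1 with shRARRES2_3, 1 with all 3 and 38 between hairpins. With log2(CPM + 0.25) shRARRES2_1 had 12. With no filter on low values the first counts were 13 and 2, and with a CPM of at least 5 shRARRES2_1 had 14, where the number of genes tested differs by construction. With libraries summing to a common total they were 6 (4 up, 2 down) and 2 (0 up, 2 down). With only the groups compared they were 64 and 2, with 0 between hairpins. edgeR gave 3 and 4, and 20 between hairpins, with GPR1 reversed for shRARRES2_2 at -0.086. DESeq2 gave 497, 345 and 16, with 2 shared and 590 between hairpins, and GPR1 at -0.080 for shRARRES2_2. In 1 simulation with independent libraries 33.1% of its calls were false, a rate that need not hold here. At an adjusted p under 0.01 there were 7 and 1, and 2 between hairpins, by construction. With the number-2 libraries of shGFP and shRARRES2_3 removed shRARRES2_2 had 29 genes and 8 lists, and KLF6 reversed for shRARRES2_1 at -0.13. With 4 paired libraries removed the counts were 149, 700 and 0, with 0 shared, 125 between hairpins, 9 lists for shRARRES2_2 and GPR1 at -0.025 for shRARRES2_1. With shRARRES2_1 replicates 2 and 3 averaged the counts of genes were 6 and 2, and 0 between hairpins. With 2 surrogate variables they were 160, 238 and 13, with 1427 between hairpins and 6 lists for shRARRES2_3; mitosis genes reversed for shRARRES2_1 (median -0.28, camera adjusted p = 0.00532), and of the 22 list calls 8 were kept and 13 ended, against 17 and 5 with the number-2 libraries removed and 14 and 8 with 4 removed. GPR1 was -0.40 for shRARRES2_1 and -0.23 for shRARRES2_2, and PLK1 -0.28 for shRARRES2_1. The lists called, 7, 5 and 10, became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with directional fry. Leaving out each library of the groups compared gave 3 to 27 genes for shRARRES2_1, 1 to 19 for shRARRES2_2 and 0 to 92 between hairpins, and 4 to 10, 5 to 9 and 7 to 16 lists. KLF6 reversed for shRARRES2_1 without shGFP replicate 2 (range -0.13 to 0.68), and for shRARRES2_2, where it was -0.01 (range -0.54 to 0.27), without shGFP replicate 1 (0.24), shGFP replicate 3 (0.27), shRARRES2_2 replicate 1 (0.01) or replicate 3 (0.08). Except where fewer genes, fewer libraries or a stricter threshold show it by construction, the cause was not tested. With a replicate block the counts were 21, 10 and 1, with 53 between hairpins, and 17, 6 and 1 of these were among the 26, 7 and 1, and 36 among the 38; the samples share only a number, 11 of 18 same-numbered pairs had r over 0.1 (for shGFP with shRARRES2_3 each of the 3, at 0.272, 0.604 and 0.518, and for shRARRES2_1 with shRARRES2_3, at 0.754, 0.490 and 0.413, which neither the F-test nor the drawn splits took into account), and 8 of 12 libraries lay closest to one of their number. Of 1128 values of named genes under other settings 1008 were the same, 95 weaker, 18 stronger and 7 reversed, and of 438 under leave-out fits 342, 89, 2 and 5. The mean of the 3 hairpins against shGFP called 1 gene, RARRES2. Depth limits genes of low level, since 3 reads correspond to 0.131 to 0.223 CPM.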

Other observations

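The lists of small nucleolar RNA host genes and keratinocyte markers, and the test of the host genes as a class, were chosen after the result was seen; the scan of 3' untranslated regions was not, but its tests of called genes and of EPAS1 were written once the overall scan was known and before the sites of these genes were looked at. Host genes of small nucleolar RNAs, whose spliced transcripts are degraded during translation, were looked at because GAS5, ZFAS1 and C6orf48 had been called with shRARRES2_1. Over all 19 members the median log2 changes were -0.91, -0.35 and -0.62 with shRARRES2_1, shRARRES2_2 and shRARRES2_3, with 17, 12 and 16 below 0, and no p is given for a list built on its own leading genes. Without the 4 members that drew attention, 13, 8 and 12 of 15 were below 0 (medians -0.69, -0.29 and -0.31; camera unadjusted p = 0.0111, 0.306 and 0.0285 with an estimated correlation). No test compared the hairpins. The share of non-coding transcripts was 2.17% to 2.54% in the controls, 0.959%, 1.87% and 1.86% with shRARRES2_1, 1.73%, 1.34% and 1.66% with shRARRES2_2, and 0.982%, 2.94% and 1.71% with shRARRES2_3. The lowest medians of the class, -1.09 and -0.88, were in the libraries with the lowest shares, shRARRES2_1 and shRARRES2_3 replicates 1, whereas shRARRES2_3 replicate 2, with the highest share, had -0.55. The cause was left open.

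Keratin genes of basal keratinocytes were far higher in 1 control library than in the other 11 libraries. In shGFP replicate 2 KRT5 had 169 CPM, KRT14 119 CPM, KRT6A 99.3 CPM and COL17A1, a hemidesmosome collagen, 54.6 CPM. In the other 11 libraries KRT5 was at or below 8.18 CPM and COL17A1 at or below 10.1 CPM. Among the other controls, KRT5 was at 3.81 CPM in shGFP replicate 3 and at 0 in shGFP replicate 1. KRT10, also on the list, was at 40.1 to 113 CPM in all libraries, with 76.6 CPM in shGFP replicate 2.

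A first hypothesis was that each hairpin lowers unintended transcripts that match its seed sequence. The hairpin sequences are not in the labels, so all 7-mers in the 3' untranslated regions of 10564 genes were scanned, comparing each hairpin with the mean of the other 2. Of 16185 7-mers, 1407 (8.69%) occur in the RARRES2 messenger RNA. The 7-mer with the lowest score belonged to that messenger RNA for each hairpin: CCCAAGT for shRARRES2_1 (z = -13.2), GAAACGG for shRARRES2_2 (z = -8.24) and CCTGGAC for shRARRES2_3 (z = -8.00). Of the 84 splits of the 9 hairpin libraries, scores as low were reached by 1, 16 and 18. Whether those splits held more shRARRES2_1 libraries was not examined. By library, CCCAAGT scored -8.31, -10.1 and -9.78 with shRARRES2_1, GAAACGG -8.44, -2.19 and -6.17 with shRARRES2_2 (1.13 to 1.98 in the other 9) and CCTGGAC -7.42, -1.07 and -9.15 with shRARRES2_3 (-0.173 to 4.32 in the other 9), for 7-mers chosen from these same libraries. The 27 splits with 1 library of each hairpin reached -9.005, beyond the scores of shRARRES2_2 and shRARRES2_3, so scores of that size also arise in groupings that mix the hairpins. In these splits the leading 7-mer lay in RARRES2 in 1.

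Among genes called lower with shRARRES2_1, 5 of 6 with a searched region held a site of the 3 leading 7-mers, against 27.3% of 10558 other genes (exact two-sided Fisher p = 0.00707). These were MTPN, MARCKSL1, RAB1A, PRKRA and AP3M1, with regions of 683 (PRKRA) to 3555 nucleotides (AP3M1). C6orf48 held none in 103 nucleotides. A longer region is more likely to hold a site, and the test took no account of length. Seed matches of this hairpin may account for part of its lower genes. With shRARRES2_2 it was 1 of 5, against 9.57% (exact two-sided Fisher p = 0.396). The scan for these tests left out the called genes.

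The site among shRARRES2_2 genes was in EPAS1. In a scan without the called genes and HIF targets, its 3' untranslated region held 3 overlapping matches at 1 place in 2043 nucleotides; 9.10% of other genes had a match. A seed match of the hairpin could thus lower EPAS1 directly, and with it HIF targets, of which 3 of 24 had a match themselves. EPAS1 was also lower, without a call, with shRARRES2_1 and shRARRES2_3 (log2 changes -1.22 and -0.79). A match of shRARRES2_2 does not bear on those levels. The 5 called genes of shRARRES2_2 as a set gave an exact two-sided Fisher p = 0.396, the hairpin sequence is unknown and 1 gene cannot test the idea further.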
